A study of Mus musculus with 10 samples.

How the data were processed

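Gene expression was measured in the liver of 5 wild-type (WT) and 5 Nr1d1 knockout (KO) male mice. Nr1d1 encodes the nuclear receptor Rev-erb alpha, a repressor of the circadian clock. Per the labels' protocols, the mice were 10 to 12 weeks old, lived in 12 h of light and 12 h of dark, and were killed 10 h after lights on (ZT10). The KO line had been backcrossed to C57Bl/6 for at least 7 generations, and the WT mice were bought. Genotype and origin of the mice therefore cannot be told apart in any comparison here. Each RNA sample came from 1 mouse and was hybridized by itself to an Affymetrix Mouse Gene 1.0 ST array.

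The authors deposited a table of normalized intensities with 27541 probe sets for 10 arrays. RMA and Partek are named per the submitters' processing notes, without versions. RMA corrects background, brings arrays to one distribution and summarises probes into probe sets, and its usual output is on a log2 scale. The deposited intensities were on a linear scale, from 8.93 to 18280, so log2 was taken first. Whether rows had been filtered before deposit is not given in the sources used here. The lower quartile of an array's log2 values lay between 6.00 and 6.11 and the upper between 8.90 and 8.99, so the arrays did not share one exact distribution. The median intensity of an array lay between 156 and 165, and the table holds no detection calls, so signal over background is unknown. The number of arrays limits the precision.

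Probe sets were named through a table of the array's annotation. Of all probe sets, 21631 had 1 gene symbol, 1317 had several and 4593 had none in that table. Gene IDs of 21544 of the first kind were found in a RefSeq gene table of assembly GRCm38.p6, and 0 symbols needed an update. That table was used only for names and for the order of genes, since the build behind the array annotation was not matched to it. Only probe sets with 1 symbol were tested, with the probe set of the highest mean over the 10 arrays standing for each of the 951 genes that had more. This left 19933 genes.

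KO was compared with WT by limma (version 3.58.1, R 4.3.3) with lmFit and eBayes on log2 values, two-sided, without covariates. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested, and genes changed by at least 1.5-fold were also counted. Differences are KO minus WT on the log2 scale, with the standard error (SE) of the fit. Groups are given as mean ± SD. Every adjusted p given for a gene comes from limma. These limma p-values measure the spread between these mice.

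Before the data were examined, 30 gene lists with 462 entries were fixed, of which 410 entries matched a tested gene. They cover 2 clock lists, lipid, cholesterol, bile acid, lipoprotein, glucose, heme and drug metabolism, sex-biased liver genes, heat shock, the unfolded protein response, acute phase, immediate early and cell cycle genes, corepressors and liver factors, secreted hepatocyte proteins, and markers of 9 other cell types or tissues. The 29 lists with at least 5 measured genes were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. At the preset correlation camera ranks a list against other genes, so its p does not measure how a list varies between mice. Camera with a correlation estimated from the data, and fry, were run beside it. Means of the marker lists were also compared by exact two-sided permutation over the 252 assignments of arrays, for which the smallest possible p is 0.00794. Counts adjusted over the list alone use the same limma p-values, adjusted within that list.

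The genes named in the text were also fixed by rule beforehand. They are Nr1d1, the 12 largest increases and 12 largest decreases among called genes whose KO arrays all lay on one side of all WT arrays, every measured gene of the clock lists, and up to 4 genes of each other list by smallest adjusted p. Clone and model names and probe sets with several symbols were left out of the largest changes. Other genes are named where a count is small, and the text then says that they were chosen after their values were seen. The genes next to Nr1d1 on its chromosome were compared with all other genes by Fisher's exact test, with 100 measured genes taken on each side. That test counts genes as independent units.

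The limma and camera steps were tested on simulated data of 19933 genes with the real means and spreads and 200 changed genes. Of genes changed by 0.5, 1 and 1.5 on the log2 scale, 90.9%, 98.5% and 100% were recovered with the right sign. Of the calls, 4.46% were false. Changes smaller than 0.5 were not simulated, while the median size of the real changed genes was 0.37, so recovery at such sizes is unknown. With no list shifted, camera called 0 lists in that simulation, in which genes were drawn independently.

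The alternatives tried were all probe sets with a symbol, the mean of a gene's probe sets, a filter on dim genes, centring on array medians, repeated quantile normalization, eBayes with trend and robust options, array weights, the numbers in the sample titles as covariates, and each array left out in turn. The meaning of the title numbers is not given in the sources used here. The first of them is fully ordered by genotype, so it was used only within genotype and cannot adjust the difference between the genotypes. The spread of an array (interquartile range, IQR, of its log2 values) as a covariate, and a fit without the 3 arrays of widest IQR, were added after seeing the data. Tables were handled and figures drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.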

Results

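Rev-erb alpha, the product of Nr1d1, represses transcription in the liver during the light phase. The design asks which liver transcripts differ when it is missing late in the light phase, at ZT10. Arrays of 5 WT and 5 KO male mice were compared, 1 mouse per array. Arrays of the same genotype correlated with r between 0.994 and 0.998, and arrays of different genotype with r between 0.990 and 0.995, over genes, which are not independent replicates. The first principal component held 39.8% of the variance and separated the genotypes. The second held 17.1%, and on it WT replicate 1 and KO replicates 4 and 5 lay apart from the others, at scores of 8.75 to 15.3. These were also the 3 arrays of widest IQR, at 2.98, 2.96 and 2.99 on the log2 scale.

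The targeted gene itself was not lower in the KO livers. The only Nr1d1 probe set (10390691) read 9.78 ± 0.16 in WT and 9.92 ± 0.45 in KO (log2 intensity, SD, n = 5 each), a limma difference of 0.14 with SE 0.18 and adjusted p = 0.803. Single WT livers read 10.00, 9.80, 9.60, 9.85 and 9.64, and single KO livers 9.29, 9.77, 10.54, 9.95 and 10.04. Whether this probe set covers the deleted part of the gene is not given in the sources used here, and a probe set outside it checks nothing about the genotype. Thra, the thyroid hormone receptor gene that overlaps Nr1d1 at its end, fell by 0.33 (SE 0.086, adjusted p = 0.0414), a call lost without any 1 of 8 arrays (adjusted p up to 0.101).

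Clock genes that carry binding elements for Rev-erb and ROR receptors rose in KO liver. Arntl, which encodes the core clock activator BMAL1, rose 4.38-fold, from 7.30 ± 0.24 to 9.43 ± 0.29 (log2 intensity, SD, n = 5 each), and every KO liver lay above every WT liver. Its limma difference was 2.13 with SE 0.14 and adjusted p = 3.2e-06. Clock, the partner of BMAL1, rose by 0.83, the repressor Nfil3 by 1.15 and the clock repressor Cry1 by 0.56. All 4 measured genes of this list rose, also when adjusted over the list alone. With fewer than 5 genes the list was not given to camera. Its mean was higher in KO in the exact permutation test (p = 0.00794, the smallest possible, adjusted p = 0.0265 over all 30 lists). This test had been planned for the marker lists only. The lists of lipid droplet, fatty acid oxidation, lipoprotein, drug metabolism, male-biased, female-biased, unfolded protein response and cell cycle genes reached the same p. Of other lists called by camera, heat shock (adjusted p = 0.0649), cholesterol (0.175), immediate early (0.179) and sinusoidal endothelial (0.313) did not pass it. The call of Cry1 was lost without any 1 of 3 arrays (adjusted p up to 0.0567) and without the 3 arrays of widest IQR (adjusted p = 0.0853).

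Clock genes driven by E-boxes or D-boxes mostly did not pass the test at this time of day. Of 14 measured, Hlf rose by 0.35, while Wee1, a kinase that delays mitosis, fell by 0.75 and the period gene Per2 fell by 0.50. The other 11 did not pass, among them Dbp at -0.01, Nr1d2, the paralog of Nr1d1, at -0.06, Per1 at -0.12 and Per3 at -0.22. Adjusted over the list alone, 1 gene was higher and 3 were lower. Camera gave the list an adjusted p of 0.0721, and adjusted p = 0.462 with an estimated correlation. The list passed at the preset correlation without WT replicate 2 (adjusted p = 0.0478), WT replicate 4 (0.0148), KO replicate 4 (0.0391) or KO replicate 5 (0.0248), without the 3 arrays of widest IQR (0.0180) and with array weights (0.0282). The call of Per2 was lost without any 1 of 6 arrays (adjusted p up to 0.0693) and without the 3 arrays of widest IQR (adjusted p = 0.160).

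**Figure D1:**
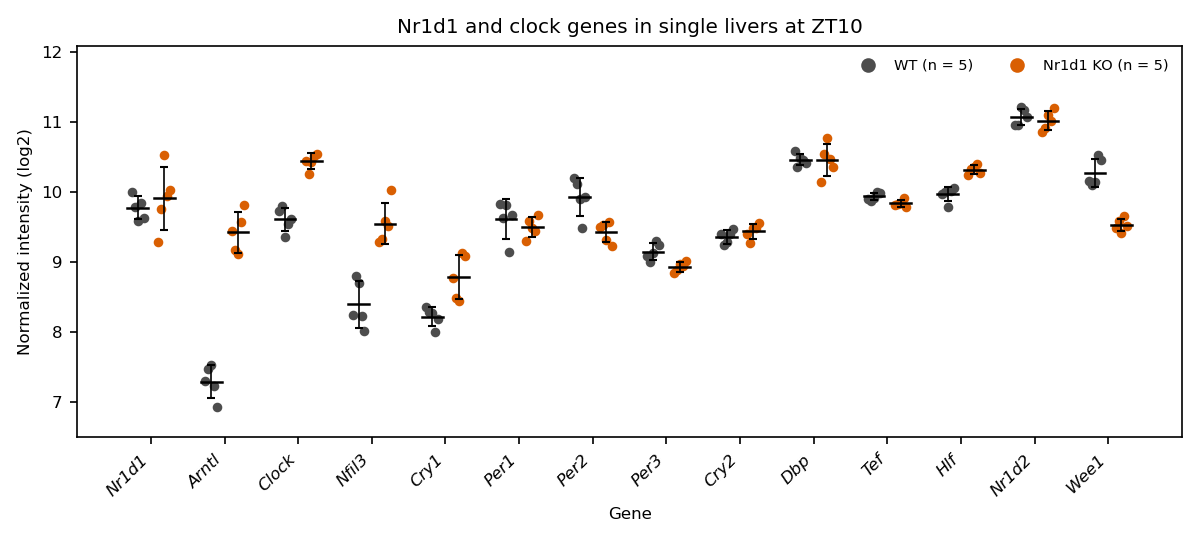
Normalized log2 intensity of Nr1d1 and 13 clock genes in single livers at ZT10, with WT in grey and Nr1d1 KO in orange, each point 1 mouse (n = 5 per genotype), wide bars the mean and thin bars 1 SD. The lowest KO liver lies 1.58 above the highest WT liver in Arntl, while the genotypes overlap in Nr1d1.

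Across the liver transcriptome 1119 of 19933 genes changed (5.61%), 632 of them higher and 487 lower in KO. The change reached 1.5-fold in 265 genes, of which 162 were higher and 103 lower. The median size among changed genes was 0.37 on the log2 scale. In 957 changed genes the KO and WT arrays did not overlap, and over all genes this held for 7.00% against 0.794% by chance. Without the 3 arrays of widest IQR, 527 genes changed, 471 of them among the 1119.

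The largest increases were in Cyp2b9 and Cyp2b13, members of the cytochrome P450 2b family. Cyp2b9 rose from 8.04 ± 1.46 to 13.13 ± 0.19 (log2 intensity, SD, n = 5 each), a difference of 5.09 with SE 0.53 (limma adjusted p = 0.000145), and Cyp2b13 rose by 4.62. The Cyp2b genes are close paralogs, so signal could be shared between their probe sets and their single values are uncertain. In WT livers the mean of Cyp2b13 (5.04) lay below the lower quartile of every array and near Xist (5.02), which male liver does not express. So did that of Sult1e1 (5.27), though WT replicate 2 read 6.15, above its lower quartile of 6.04. Neither WT mean is shown to be above background, and the sizes of both rises are uncertain. The estrogen sulfotransferase Sult1e1 rose by 3.98, the steroid 17-alpha-hydroxylase Cyp17a1 by 2.77, the acyltransferase Acnat2 by 2.45, Cyp2b10 by 2.43 and the fatty acid hydroxylase Cyp4a14 by 1.95. Arntl, the metallothionein Mt1 (1.91), the mitochondrial chaperone Clpx (1.89), the glycogen-targeting phosphatase subunit Ppp1r3c (1.85) and Chic1 (1.82) complete the 12 largest increases.

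Asns, the asparagine synthetase, showed the largest decrease. It fell by 2.84, from 9.47 ± 0.26 to 6.63 ± 0.087 (log2 intensity, SD, n = 5 each, SE 0.10, limma adjusted p = 2.3e-08). Serpina4-ps1 fell by 2.57, the small heat shock gene Hspb1 fell by 1.87, the guanylate-binding gene Gbp11 fell by 1.76, and the differences of the transglutaminase Tgm1 and of Cabyr were -1.65 and -1.62. Nat8f5 fell by 1.53, Adgrf1 by 1.45, the selenium-binding gene Selenbp2 by 1.44, the growth factor gene Nrg4 by 1.35, Tmeff2 by 1.31 and Lonrf1 by 1.30. Without the 3 arrays of widest IQR the calls of Hspb1 (adjusted p = 0.0885) and Adgrf1 (adjusted p = 0.0653) were lost with fewer arrays in the fit, at differences of -1.86 and -1.43.

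Most genes with known male bias in mouse liver fell, and some with female bias rose, in these male KO mice. Of 14 male-biased genes, 11 fell, 1 rose and 2 did not pass, and the counts were the same when adjusted over the list alone. Selenbp2 fell by 1.44, the oxysterol hydroxylase Cyp7b1 by 0.93 and the organic anion transporter Slco1a1 by 0.68. The exception was the fatty acid elongase Elovl3, which is male-biased and rose by 1.32. Of 11 female-biased genes, Cyp2b9, Cyp2b13, Cyp17a1 and Hao2 rose and 7 did not pass, with 5 higher when adjusted over the list alone. Hao2, at 5.20 in WT and 5.42 in KO, lay below the lower quartile of every array in both genotypes. The mean of the female-biased list was 1.19 and its median 0.12, so a few large changes carried the mean. Camera gave adjusted p = 7.1e-12 for the male-biased and 5.2e-06 for the female-biased list. Both kept the call with an estimated correlation (adjusted p = 0.0127 for each), and no other list did. The call of Hao2 was lost without the 3 arrays of widest IQR (adjusted p = 0.0987).

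Genes of fatty acid oxidation and PPARalpha targets rose in part. Of 23 measured, 7 rose and 16 did not pass, and 11 were higher when adjusted over the list alone. Cyp4a14 rose by 1.95, the pantetheinase Vnn1 by 1.06, Cyp4a10 by 0.72 and the dehydrogenase Acadm by 0.33. The camera adjusted p was 4.7e-09, and adjusted p = 0.372 with an estimated correlation. Among 16 lipid droplet genes, the droplet coat genes Plin5 (0.75) and Plin4 (0.49) and the fatty acid transporter Cd36 (1.57) rose and 13 did not pass. For that list 4 were higher when adjusted over the list alone, with a camera adjusted p of 0.00266 and adjusted p = 0.462 with an estimated correlation. The calls of Plin4 (adjusted p = 0.0880) and Acadm (adjusted p = 0.0643) were lost without the 3 arrays of widest IQR.

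Drug and steroid metabolism genes also rose in part, 7 of 21 with 14 not passing, and 11 were higher when adjusted over the list alone. The glutathione transferase Gstt3 rose by 1.15, Cyp2b10 by 2.43, Cyp2c37 by 0.41 and the sulfotransferase Sult1d1 by 0.46. The camera adjusted p was 1.5e-07, and adjusted p = 0.372 with an estimated correlation. Of 21 apolipoprotein and lipoprotein genes, Lpl, which encodes lipoprotein lipase, rose by 0.98, Apoa4 by 1.06 and the HDL receptor Scarb1 by 0.54, and 18 did not pass. Adjusted over the list alone, 5 were higher and 2 lower, and camera gave an adjusted p of 0.0253, with adjusted p = 0.441 with an estimated correlation. The camera call of the lipoprotein list was lost without WT replicate 2 or WT replicate 3 (adjusted p up to 0.0612) and without the 3 arrays of widest IQR (adjusted p = 0.0760), where Sult1d1 also lost its call (adjusted p = 0.110).

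Cholesterol synthesis genes were lower as far as they passed. Of 20 measured, Cyp51 fell by 0.67, Fdps by 0.52, the sterol transporter Stard4 by 0.50 and Lss by 0.40, while 16 did not pass, and 7 were lower when adjusted over the list alone. The camera adjusted p was 5.2e-06, and adjusted p = 0.462 with an estimated correlation. Among 22 genes of fatty acid and triglyceride synthesis, the elongase Elovl6 fell by 0.95, the citrate lyase Acly by 0.59 and the desaturase Fads2 by 0.20. Mogat1 rose by 0.38, as did Agpat2 by 0.21, which was chosen after its values were seen and lost the call in 15 settings (adjusted p up to 0.119), and 17 did not pass. Adjusted over the list alone, 3 were higher and 5 lower, and the camera adjusted p was 0.329. With 1 array fewer in the fit, the calls of Cyp51 (4 arrays, adjusted p up to 0.0707), Fdps (2 arrays, up to 0.0658), Lss (6 arrays, up to 0.0887) and Fads2 (1 array, WT replicate 2, 0.0520) were lost, while their differences kept 0.843 to 1.03 times their size. Without the 3 arrays of widest IQR these 4 and Acly (adjusted p = 0.0684) lost the call, and the mean of the cholesterol list was -0.12 against -0.25.

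Bile acid genes went both ways, with 3 of 22 higher, 3 lower and 16 not passing, and 6 higher and 4 lower when adjusted over the list alone. The bile salt export pump Abcb11 rose by 0.43 and the oxidase Acox2 by 0.48, while Cyp7b1 fell by 0.93 and Slco1a1 by 0.68. The remaining changed genes, chosen after their values were seen, were Hsd3b7 (0.52) and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, which fell by 0.93 (adjusted p = 0.0379). Cyp7a1 lost the call in 10 settings (adjusted p up to 0.227), of which 7 left out 1 array. The camera adjusted p was 0.332. Of 13 gluconeogenesis genes, the aminotransferase Gpt rose by 0.28 and the carboxylase Pcx by 0.21, 11 did not pass, the count was the same adjusted over the list alone, and the camera adjusted p was 0.329. Of 14 glycolysis and glycogen genes, Ppp1r3c rose by 1.85 and Ppp1r3b by 0.77, while Pfkfb3 fell by 1.30 and the glycogen synthase Gys2 by 0.30, and 10 did not pass. Adjusted over the list alone, 4 were higher and 3 lower. The mean of that list was 0.05 and its median -0.01, with the camera direction up at an adjusted p of 0.770. Of 11 heme genes, Hmox2 rose by 0.34 and Cpox by 0.30, 9 did not pass, 2 were higher and 2 lower when adjusted over the list alone, and the camera adjusted p was 0.957. The calls of Pcx (any of 10 arrays, adjusted p up to 0.0933), Cpox (7 arrays, up to 0.0860), Gys2 (3 arrays, up to 0.0571) and Pfkfb3 (2 arrays, up to 0.0567) were lost when single arrays were left out. These 4 and Gpt (adjusted p = 0.0618) lost it without the 3 arrays of widest IQR.

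**Figure D2:**
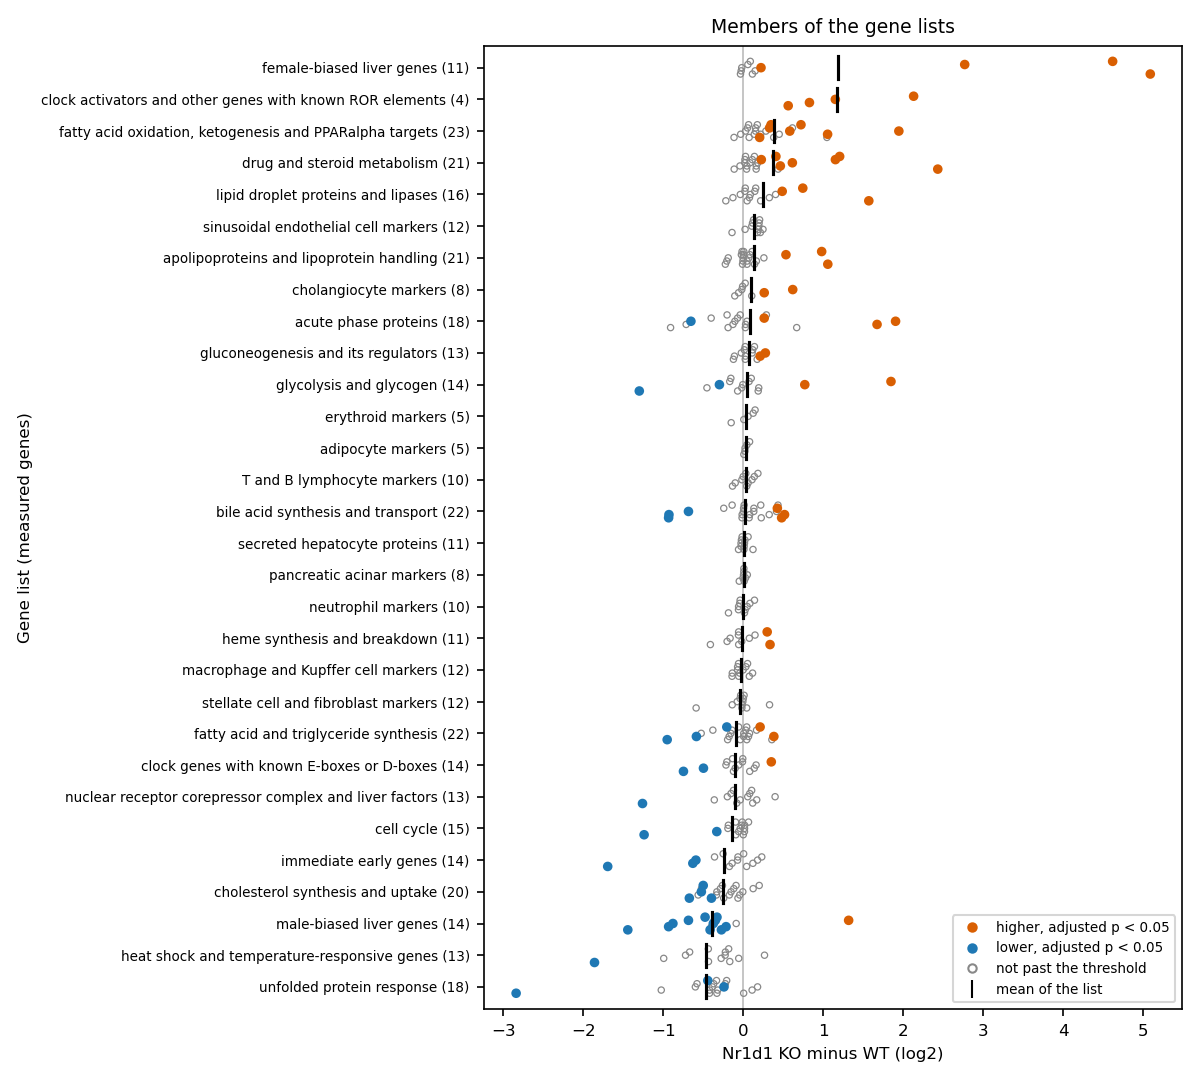
Log2 difference, KO minus WT, of each measured gene of the 30 lists, ordered by list mean. Filled points passed the limma threshold, in orange where higher and blue where lower in KO, open points did not, black bars are list means, and the number after each name is its measured genes. In the male-biased list 11 of 14 genes are lower, and in the female-biased list 4 of 11 are higher.

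Unfolded protein response genes were lower as far as they passed. Of 18 measured, Asns fell by 2.84, the chaperone gene Pdia6 by 0.44 and the transcription factor gene Atf4 by 0.24, and 15 did not pass. Asns and Atf4 also belong to the amino acid response. Adjusted over the list alone, 15 were lower. The camera adjusted p was 4.7e-09, and adjusted p = 0.372 with an estimated correlation. Of 13 measured genes of the heat shock and temperature-responsive list, Hspb1 fell by 1.87 and 12 did not pass. The count was the same adjusted over the list alone. This list also holds Cirbp, Rbm3 and Creld2, so its values do not stand for heat shock genes alone. Hspa1b, an entry of this list, could not be tested by itself. The probe set it shares with Hspa1a fell by 0.84 (limma adjusted p = 0.0339). That list had a camera adjusted p of 2.7e-05, and adjusted p = 0.372 with an estimated correlation. WT livers varied more than KO livers in 13 of 13 genes of that list and 16 of 18 unfolded protein response genes. The calls of Atf4 (6 arrays, adjusted p up to 0.0665) and Pdia6 (7 arrays, up to 0.0829) were lost when single arrays were left out, and without the 3 arrays of widest IQR (adjusted p = 0.102 and 0.235).

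Immediate early genes and the cell cycle genes that could be tested singly fell in small numbers. Of 14 immediate early genes, Myc fell by 1.69, Jun by 0.63 and Btg2 by 0.59, and 11 did not pass, the same count as adjusted over the list alone. Camera gave an adjusted p of 0.0253, and adjusted p = 0.580 with an estimated correlation. Of 15 cell cycle genes, the cyclin Ccnd1 fell by 1.24 and Mcm6 by 0.33, and 13 did not pass, with 3 lower when adjusted over the list alone. Cdkn1a, an entry of this list left out because its probe set is shared with 4930567H12Rik, could not be tested by itself, and the shared probe set rose by 3.75 (adjusted p = 1.0e-06). Camera gave an adjusted p of 0.0344, and adjusted p = 0.462 with an estimated correlation. Both list calls were lost when single arrays were left out, the first for 4 arrays (adjusted p up to 0.116) and the second for 3 (up to 0.188). So were the calls of Jun (8 arrays, up to 0.0936), Btg2 (2 arrays, up to 0.0548) and Mcm6 (6 arrays, up to 0.103). The cell cycle list (adjusted p = 0.363) and Mcm6 (0.0618) also lost the call without the 3 arrays of widest IQR.

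Acute phase genes went both ways. Of 18 measured, Mt1 rose by 1.91, Mt2 by 1.67 and the copper carrier gene Cp by 0.26, the serum amyloid P gene Apcs fell by 0.65, and 14 did not pass. Adjusted over the list alone, 3 were higher and 4 lower. The mean of the list was 0.08, its median -0.05 and its camera direction down, at an adjusted p of 0.666. Among 13 genes of corepressors and liver factors, Onecut1 fell by 1.26 and 12 did not pass, with Hdac3 at 0.17, and 2 were higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.666). None of 11 genes of secreted hepatocyte proteins passed in limma, over all genes or adjusted over the list alone, and camera gave an adjusted p of 0.957. Onecut1 (7 arrays, adjusted p up to 0.0798) and Mt2 (2 arrays, up to 0.0538) lost the call when single arrays were left out. Onecut1 (adjusted p = 0.183) and Apcs (0.0620) also lost it without the 3 arrays of widest IQR.

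Among the marker lists of other cell types, that of cholangiocytes gave the smallest p in the exact permutation test (difference 0.10, p = 0.0159). Its adjusted p was 0.143 over the 9 marker lists, the adjustment fixed beforehand, and 0.0476 over all 30 lists, the adjustment given above for the clock activators. No other marker list passed in the exact test with either adjustment. Of those 8 genes, Sox9 rose by 0.62 and Pkhd1 by 0.26, and 6 did not pass, with 2 higher adjusted over the list alone, a median of 0.01 and a camera adjusted p of 0.331. For sinusoidal endothelial markers the mean difference was 0.14 (exact permutation p = 0.198), 0 of 12 genes passed over all genes or adjusted over the list alone, and the camera adjusted p of 0.0169 became adjusted p = 0.683 with an estimated correlation. That camera call was also lost without any 1 of 4 arrays (adjusted p up to 0.189) and without the 3 arrays of widest IQR (adjusted p = 0.0840), where Sox9 (0.0666) and Pkhd1 (0.0730) lost theirs. Pkhd1 also lost it without any 1 of 5 arrays (adjusted p up to 0.0896). In the lists for macrophages and Kupffer cells (mean difference -0.02), stellate cells and fibroblasts (-0.04), lymphocytes (0.03), neutrophils (-0.01), erythroid cells (0.04), adipocytes (0.04) and pancreatic acini (0.01), limma called 0 genes over all genes or adjusted over the list alone. Their camera adjusted p lay between 0.504 and 0.957. Amy2b, an entry of the acinar list, could not be tested by itself. The probe set it shares with Amy2a2 and Amy2a5 rose by 0.37 (limma adjusted p = 0.0245).

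Genes next to Nr1d1 were not found changed more often than others. Of 200 neighbours, 10 changed (5%), against 5.63% of all other genes (odds ratio 0.883, 95% interval 0.415 to 1.67, Fisher's exact p = 0.877). Stat5b (0.72) and Stat5a (0.42), which carry growth hormone signals, were among the 10 and rose, and were chosen after their values were seen.

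**Figure D3:**
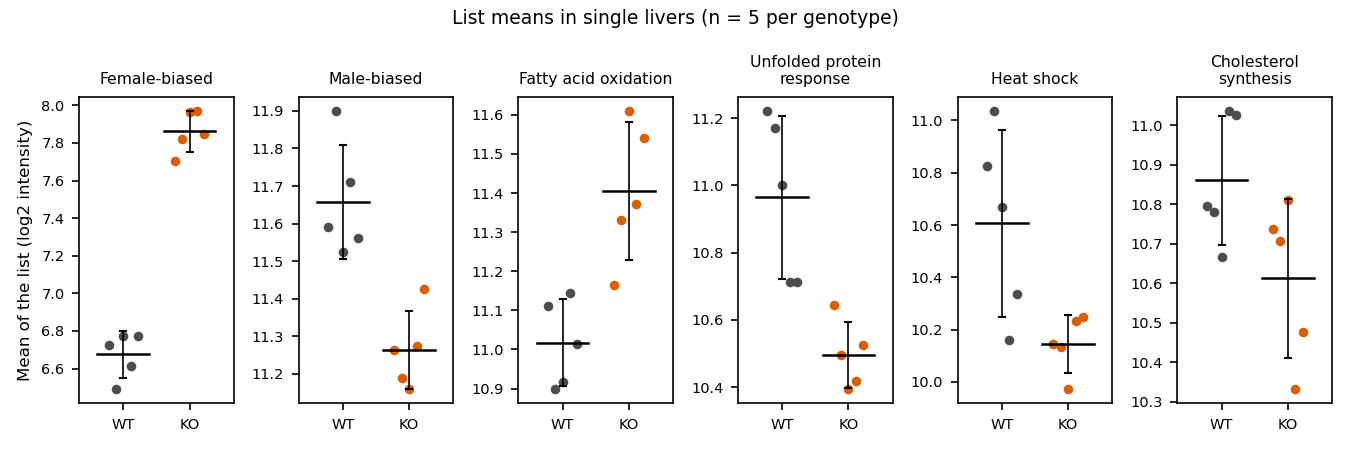
Mean log2 intensity of 6 gene lists in single livers, WT in grey and Nr1d1 KO in orange, each point 1 mouse (n = 5 per genotype), wide bars the mean and thin bars 1 SD, with a separate axis per list. Means of the heat shock and temperature-responsive list run from 10.16 to 11.04 in WT and from 9.97 to 10.25 in KO livers.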

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

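The tests with Arntl, Thra and the list without Cyp2b genes were chosen only after the results they bear on were seen, as were the IQR as a covariate and the cholesterol list without the 3 arrays of widest IQR. Refitting limma on 100 of the 126 splits of the 10 arrays argued against chance for the counts of genes. For changed genes, 1 of 100 splits reached 1119, the real one, and the highest other gave 2. The same held for 632 higher and 487 lower genes (1 of 100 each, highest other 2 in one direction) and for 265 genes changed by at least 1.5-fold (1 of 100, highest other 1). For gene lists past camera's threshold, 3 of 100 splits reached 12, namely the real one and 2 others, the highest with 14. This was under the bound of 5 splits set in advance. But another split gave more lists than the real one, so chance is not excluded for the number. Both others were among the 17 splits run that kept 4 of the 5 WT arrays together. The 82 splits that kept only 3 together gave at most 10. Every split other than the real one put 1 to 14 lists past the threshold, while calling at most 2 genes. The number of lists therefore does not exclude chance for any single list called at the preset correlation. With an estimated correlation, 1 of 100 splits reached the real 2 lists, and the highest other gave 1.

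Nr1d1 was not lower in KO (difference 0.14, adjusted p = 0.803). Mislabelled or swapped arrays are argued against by Arntl, where the lowest KO array lay 1.58 above the highest WT array, with SDs of at most 0.293. Signal from the overlapping gene Thra cannot be told apart from Nr1d1 signal with 10 arrays. After centring each genotype, Pearson's r between the probe sets was -0.309 (permutation p = 0.265, 0.131 one-sided), Spearman's rho -0.382 (permutation p = 0.293), and r -0.317 without the 2 arrays farthest from the Nr1d1 median. A transcript without the deleted part may still carry this probe set, which stays untested because the probe positions were not used here.

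Of 14 male-biased genes 11 fell, and of 11 female-biased genes 4 rose and 7 did not pass. Female tissue among the KO arrays is argued against by Xist, whose difference had an upper 95% bound of 0.0983, and 3 Y-linked genes had a mean difference of 0.06. Shared signal of the Cyp2b genes does not carry the female-biased list alone, since the 9 genes without them gave p = 0.0132 in camera with an estimated correlation. But only 2 of the 9 changed, Cyp17a1 and the dim Hao2. The median of the 9 was 0.09 against a mean of 0.37, and Cyp17a1 carried most of that mean. Array spread is argued against for the male-biased list, where 11 of the 11 lower genes kept the call with the IQR as a covariate. The genotype and a difference in origin between the bought WT mice and the KO line both stay open, and no test here separates them. The same holds for every other difference between the groups reported here.

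Of 18 unfolded protein response genes 3 passed as lower, and of 20 cholesterol genes 4 did, while 15 and 18 had negative differences. The mean of both lists together was -0.35 (SE 0.064). Neither list passed camera with an estimated correlation (adjusted p = 0.372 and 0.462). Array spread as the whole cause is argued against, since with the IQR as a covariate the shift was -0.37 (SE 0.066), 1.04 times its size, but it stays open for the cholesterol list, which kept 0.504 of its mean without the 3 arrays of widest IQR. A single array is argued against for both lists together, since leaving out each in turn kept at least 0.869 of the shift, the lowest without KO replicate 4. That share is not given for the cholesterol list by itself. The cholesterol list kept its camera call at the preset correlation with any single array left out. That p does not measure how the list varies between mice, so a single array stays open there. In replicate order, the means of the cholesterol list in KO livers were 10.74, 10.71, 10.81, 10.33 and 10.48. Those of WT livers ran from 10.67 to 11.04, so the lists' KO and WT livers overlapped for cholesterol genes. WT livers scattered in the heat shock and unfolded protein response lists, and whether feeding, handling or body temperature differed between mice before harvest was not tested. The genotype and the origin of the mice stay open beside these, untested.

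In 22 of 344 groups of 5 arrays the array at one end lay far from the others, 6.40% against 5.02% of simulated normal groups, so about 17.3 would be flagged by chance. The gap to the nearest array, as a share of the group's range, is given for each. In KO replicate 3 it was 0.747 for Cyp2b10, 0.739 for Nat8f5, 0.739 for Mgll, 0.728 for Pcx, 0.846 for Blvrb, 0.873 for the mean of the lipoprotein list and 0.748 for that of the drug metabolism list. In KO replicate 4 it was 0.775 for Gbp11, 0.727 for Marco and 0.739 for Hrg, in KO replicate 5 0.916 for Nrg4 and 0.863 for Foxo1, in KO replicate 1 0.772 for Cyp4a14 and in KO replicate 2 0.844 for Cftr. In WT replicate 3 it was 0.754 for Cyp2b10, 0.810 for Clec4f and 0.827 for Csf3r, in WT replicate 4 0.716 for Per1 and 0.734 for Alas1, in WT replicate 1 0.807 for Fcgr2b and 0.838 for the mean of the cell cycle list, and in WT replicate 2 0.863 for Acly.

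Probe sets outside the comparison also differed between the genotypes. Of 4593 probe sets with no symbol, 71 changed in limma (1.55%), and of 1317 with several symbols, 46 changed (3.49%), 15 higher and 31 lower. The largest, a probe set shared by 4930567H12Rik and Cdkn1a, rose by 3.75 (adjusted p = 1.0e-06), and one shared by Gstp1 and Gstp2 fell by 1.18. They cannot be assigned to 1 gene.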

How the results depend on the processing

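The fit with the IQR as a covariate and the fit without the 3 arrays of widest IQR were chosen after seeing the data. None of the 142 genes named by the rule, the 27 others named and the 29 lists that were refitted changed direction past its threshold. Gene families were not refitted, and the filter on dim genes left out 1 of the 27 others and kept 112 named genes besides Nr1d1 and 21 lists. The count of changed genes stayed between 986 and 1395 in the settings that kept all arrays, and the count changed by at least 1.5-fold between 236 and 280. Centring each array on its median gave 986 genes, 50.4% of them higher against 56.5%. Without the 3 arrays of widest IQR, 527 genes changed, 295 higher and 232 lower, with fewer arrays in the fit. Of 12 lists, 2 passed with an estimated correlation and 6 with fry, which does not compare a list with other genes. Those past fry were the male-biased, female-biased, fatty acid oxidation, lipoprotein, drug metabolism and unfolded protein response lists. Leaving out each array in turn gave 805 to 1248 changed genes, 452 to 637 higher, 349 to 611 lower, 221 to 302 by at least 1.5-fold, 9 to 12 lists, 0 marker lists adjusted over the 9, a Nr1d1 difference of -0.02 to 0.29 and a neighbour odds ratio of 0.633 to 1.03. With 50 and 200 neighbours on each side the odds ratio was 0.699 and 0.882. Counting each named gene in each setting, 131 calls were lost and 33 gained, and counting each list likewise, 38 were lost and 6 gained, all 6 by clock genes with E-boxes or D-boxes. Of the 27 others, 5 lost the call in at least 1 setting (Agpat2, Cyp7a1, Thra, Igf1 and Cish), and Igfals gained it in 3. The 25 named genes that lost the call without the 3 arrays of widest IQR kept 0.685 to 1.25 times their difference, with a median of 0.951. The 18 that lost it when 1 array was left out kept 0.774 to 1.09 times theirs, with a median of 0.959. Nr1d1 had 1 probe set, so another could not be tried. No paired analysis was possible because the labels tie no WT mouse to a KO mouse. Without detection calls, signal over background limits what can be said of dim genes, such as Cyp2b13, Sult1e1, Hao2 and Mogat1.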

Other observations

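Genes outside the lists, chosen after their values were seen, also differed. Insig2, which holds back the release of SREBP from the endoplasmic reticulum, rose by 1.68 (SE 0.097, limma adjusted p = 1.1e-06), and the glycine decarboxylase gene Gldc rose by 1.33 (SE 0.053, limma adjusted p = 4.3e-08). The carbonic anhydrase gene Car14 rose by 1.63, Acss3 by 1.65, Ndrg1 by 1.66, Slc45a3 by 1.42 and the choline kinase gene Chka by 1.36. The antimicrobial peptide gene Leap2 rose by 1.14 and Hamp2 by 1.19. Nampt, the rate-limiting enzyme of NAD salvage, fell by 0.82, the estrogen receptor gene Esr1 by 1.23, the taurine synthesis gene Csad by 1.08 and the sorting receptor gene Sort1 by 0.99. In each of these 13 genes all KO livers lay on one side of all WT livers, as in 957 of the 1119 changed genes.

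Stat5b rose by 0.72 (SE 0.066, limma adjusted p = 5.8e-05) and Stat5a by 0.42 (adjusted p = 0.00163). If growth hormone signalling changed with them, its target and feedback genes may have changed too, and 2 of 6 did. The test counted changes in either direction, and both of these genes fell while Stat5a and Stat5b rose. Cish fell by 1.84 (adjusted p = 0.0169) and Igf1 by 0.23 (adjusted p = 0.0246), calls lost in 1 and 5 settings (adjusted p up to 0.0586 and 0.118). Igfals was at -0.26 (adjusted p = 0.0704), Socs2 at -1.08 (adjusted p = 0.275), Bcl6 at 0.12 and Ghr at -0.01. Socs2, Bcl6 and Cish varied widely between mice, with SDs of up to 1.06, so the test leaves the hypothesis open.

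Donor-strain DNA could remain beside the targeted gene or elsewhere. Beside Nr1d1 the odds ratio of being changed was 0.883, and its interval up to 1.67 leaves a moderate excess open. Along all chromosomes the highest count of changed genes in 50 neighbouring genes was 10, against a median of 10 over 1000 shuffles of the gene order. An intact Nnt gene in the KO line alone, a known difference between C57Bl/6 substrains, was tested by the Nnt probe set. Its difference was -0.0973 (95% interval -0.248 to 0.0535), so no rise was seen. Probe positions were not used here, and a probe set outside the part that differs would show nothing, so the test cannot decide this.

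Gene families, grouped by the stem of the symbol, were tested for moving together. Of 250 families, 0 passed camera with an estimated correlation (smallest adjusted p = 0.993), and 9 passed with the preset correlation. The bound set in advance, an adjusted p over 0.5, was met, but it was too lax, since families such as Snord, with 8 of 31 genes lower and 0 higher, did not pass either. Whether families moved together is left open.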
